A study of Mus musculus with 10 samples.

How the data were processed

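The series holds single-cell RNA libraries from mouse heart, 5 from piezo1ΔLysM and 5 from piezo1fl/fl animals. The labels name neutrophils and monocytes/macrophages as the cell types, and state no injury, time point, sort or sex. They do not say whether the samples of a group came from separate animals, so the p-values measure the spread between these samples only. Libraries were made with the Chromium 3′ v3 kit, per the labels. Per the file headers, the authors ran Cell Ranger 5.0.0, and their processing notes name Cell Ranger, STAR and the mm10 build. The deposited matrices hold raw UMI counts per gene and barcode with no normalization, 1 library per matrix, for 32285 genes. The authors' own cell filters and cell annotation were not stated. Gene positions came from GENCODE vM21 on GRCm38, the assembly that mm10 names; 99.6% of the genes had a position.

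Cells with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, 77241 of 82225 barcodes. Doublets were scored per sample with Scrublet in scanpy 1.11.5, and the highest-scoring barcodes were removed at an expected rate of 0.8% per 1000 barcodes, 5134 in all. The remaining 72107 cells were clustered on 2000 variable genes chosen within samples, 30 principal components, 15 neighbours and Leiden resolution 1, with leidenalg 0.10.2. Piezo1, Lyz2, sex-linked and mitochondrial genes were left out of the clustering. Each of the 26 clusters took a class name from a marker list alone; 3 clusters, with 9292 cells, met no list and were left unnamed. Monocytes/macrophages and neutrophils were clustered again at resolution 0.5 into 18 sub-clusters, which were named in the same way. That resolution and the naming thresholds were set after the data were examined.

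Counts were summed per sample within each class, so that the sample and not the cell was the replicate, with n = 5 per group. A sample entered a class with at least 20 cells in it, and 9 classes had at least 4 such samples in each group. The genotypes were compared with the edgeR 4.0.16 quasi-likelihood F test after TMM scaling and filterByExpr, with the Benjamini-Hochberg threshold at 0.05 within each class. CPM values (UMIs of a gene scaled by the total of the class in the sample) are on the TMM scale of the class, and log2 fold changes are piezo1ΔLysM over piezo1fl/fl. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1, at a preset correlation of 0.01, on log2 CPM, then again with an estimated correlation and with fry. The difference of the genotype effect between monocytes/macrophages and neutrophils was tested with limma on the per-sample difference of log2 CPM. Shares of cells were compared with two-sided exact permutation tests over the 252 assignments of 10 samples, whose smallest p is 0.00794.

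The tests, the 30 gene lists, the class markers, the naming rule and the first set of alternatives was fixed before the data were examined. The rule named Piezo1, Lyz2, Orai1, Rac1 and Mertk in both myeloid classes, whatever their test. It then took up to 10 genes that rose and 10 that fell past the threshold at a mean of at least 10 CPM, in the same direction with each sample left out. Of each list discussed, it took the members with the smallest p at that level. Which lists were discussed, and that 2 members of each were named, was settled after the list tests were seen. In other classes up to 3 genes each way were named.

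Alternatives of that set were DESeq2 1.42.0, limma-voom, RLE factors, no count filter, the replicate number as a block, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial UMIs), doublets kept, equal cell numbers, classes from Leiden resolution 0.5, and each sample left out in turn. For shares, immune cells as the denominator and an edgeR test on cell counts were added to these. The fits without a block remained the main results, because same-number samples did not resemble each other: 0 of 5 same-number pairs in monocytes/macrophages and 1 of 5 in neutrophils passed a correlation of 0.1. Another 6 alternatives were added after seeing the data. These were a library factor as a covariate, its first 2 components together, the 4 libraries at its ends left out, the sub-cluster of most varying share left out, the cycling sub-clusters left out, and a per-sample trend on transcript length removed. The library factor was the leading principal component of log2 CPM over 6 non-myeloid classes. Genotype was not taken out before it was computed. It was highest in piezo1ΔLysM replicates 4 and 5 (2.06 and 1.11) and lowest in piezo1fl/fl replicates 4 and 1 (-1.07 and -1.03). A fit with it as a covariate can therefore also remove a genotype effect that the classes share.

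The tests were checked on simulated data of the same size and depth. For monocytes/macrophages edgeR called 46.3% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold. For neutrophils these shares were 35.8%, 80.6% and 97.0%, and for the class difference 4.76%, 65% and 97.7%. The simulation held no library factor, which the real samples have. With a simulated length trend, 616 unchanged genes were called before the length correction and 7 after it. No pair of the 45 pairs of libraries was a duplicate: the ratio of chi-square to its degrees of freedom lay between 13.4 and 228. All matrices entered the work, and cells of unnamed clusters were left out of the gene tests because no marker list fitted them.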

Results

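Gene expression was measured in single cells of mouse heart from 5 piezo1ΔLysM and 5 piezo1fl/fl samples. Piezo1 encodes a mechanosensitive cation channel, and LysM-Cre is a Cre recombinase placed in the Lyz2 gene of myeloid cells. The series title concerns myeloid Piezo1, cardiac repair and the uptake of dying cells through Orai1 and Rac1. The samples held 57528208 to 102809328 UMIs each, and 5883 to 8398 kept cells with a median of 3342 to 6759 UMIs per cell. Monocytes/macrophages were the largest class with 25418 cells, 2102 to 2921 per sample. Neutrophils followed with 16952 cells, 1275 to 2498 per sample. Fibroblasts (7699 cells), endothelial cells (3407), dendritic cells (2894), B cells (2745), T cells (1314), mural cells (1082) and NK cells (460) also had enough cells for gene tests. Epicardial cells (410), cardiomyocytes (224), plasmacytoid dendritic cells (125) and Schwann cells (85) did not. A class name stands for clusters that met a marker list. Values below are mean ± SD over 5 samples per group unless stated otherwise.

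The first question was whether the targeted gene differed where LysM-Cre acts. In monocytes/macrophages, Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329, minus strand, GRCm38) was 32.8 ± 1.58 CPM in piezo1ΔLysM and 52.2 ± 4.48 CPM in piezo1fl/fl. It fell by 0.67 on the log2 scale (SE 0.0791, edgeR adjusted p = 0.00875), to a level 37.1% lower. The 5 piezo1ΔLysM samples lay between 30.3 and 34.4 CPM, below all 5 piezo1fl/fl samples at 47.0 to 56.6 CPM. In neutrophils Piezo1 was 15 ± 4.1 against 19.3 ± 2.89 CPM (log2 fold change -0.39, adjusted p = 0.301), with overlapping samples. In endothelial cells, where Piezo1 was most abundant of the 9 compared classes, it was 81.4 ± 4.97 against 86.3 ± 13.6 CPM (log2 fold change -0.08, adjusted p = 0.742). Fibroblasts had 25.1 ± 2.68 against 29.8 ± 2.21 CPM (log2 fold change -0.25, adjusted p = 0.241). The log2 fold change was -0.28 in B, -0.22 in mural and -0.19 in dendritic cells (adjusted p = 0.648, 0.669 and 0.490). The labels do not state which exons are floxed, and reads of a 3′ kit lie near the transcript end, so these counts do not measure the share of recombined cells. The monocyte/macrophage call ended without piezo1ΔLysM replicate 1 (log2 fold change -0.67, adjusted p = 0.0518) and with the replicate number as a block (-0.67, adjusted p = 0.135). In fits chosen after seeing the data it also ended with the library factor as a covariate (-0.67, adjusted p = 0.0552) and with the length trend removed (-0.49, adjusted p = 0.331).

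Lyz2 and Lyz1 encode lysozymes and lie 5475 bases apart on chromosome 10 (Lyz2, ENSMUSG00000069516, 117277331 to 117282321; Lyz1, ENSMUSG00000069515, 117287797 to 117292868; both minus strand). Their sequences are closely related, so reads of either could be counted for the other. In monocytes/macrophages Lyz1 rose, from 9.91 ± 6.84 CPM in piezo1fl/fl to 110 ± 13.8 CPM in piezo1ΔLysM (11.1 times as much; log2 fold change 3.47, SE 0.37, adjusted p = 0.0154). All 5 piezo1ΔLysM samples, at 90.1 to 127 CPM, lay above all piezo1fl/fl samples, at 5.47 to 22.0 CPM. Lyz2 was 5454 ± 1023 against 8625 ± 1222 CPM (log2 fold change -0.66, adjusted p = 0.248). The Lyz1 call ended without piezo1ΔLysM replicate 1 (adjusted p = 0.0577), 2 (0.123), 4 (0.136) or 5 (0.0871), and without piezo1fl/fl replicate 3 (0.0838) or 5 (0.0651), with the fold change between 3.41 and 3.49 each time. It also ended without a count filter (3.48, adjusted p = 0.154), with the replicate number as a block (3.65, adjusted p = 0.135), with the library factor as a covariate (3.71, adjusted p = 0.255) and with the length trend removed (3.32, adjusted p = 0.0842). Lyz2 passed the threshold with the length trend removed (log2 fold change -0.81, adjusted p = 0.0174) and with the library factor as a covariate (-1.03, adjusted p = 0.00107), both fits chosen after seeing the data.

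**Figure D1:**
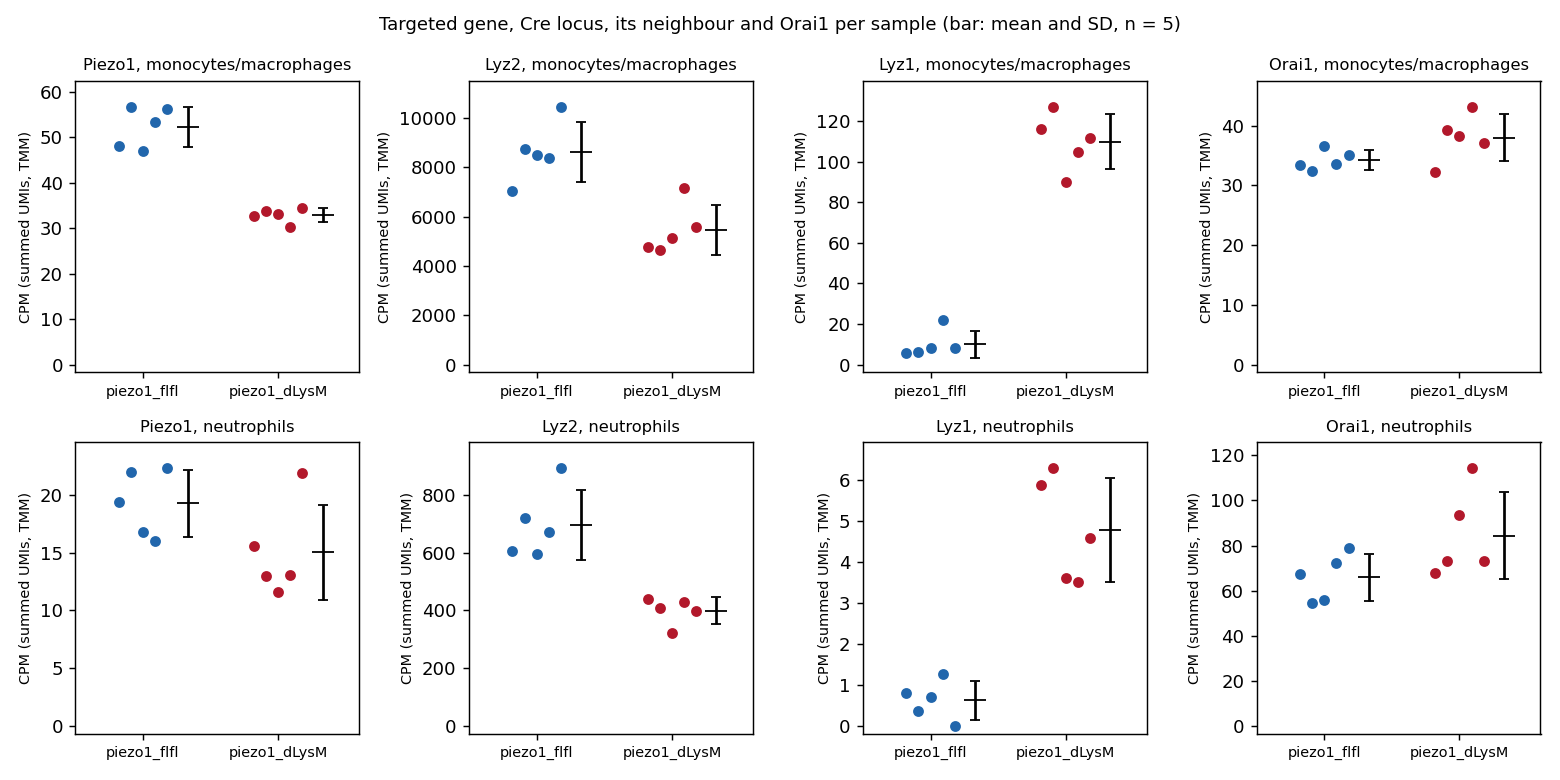
Piezo1, Lyz2, Lyz1 and Orai1 in each sample of both myeloid classes, in CPM of UMIs summed per sample on the TMM scale (y axis), by genotype (x axis; piezo1_flfl is piezo1fl/fl and piezo1_dLysM is piezo1ΔLysM). Points are samples and bars give mean and SD, n = 5; Piezo1 in monocytes/macrophages is at 30.3 to 34.4 CPM in piezo1ΔLysM and 47.0 to 56.6 CPM in piezo1fl/fl, and the same samples are apart for Lyz1.

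Over all 12883 genes tested in monocytes/macrophages, edgeR called 2: Lyz1, which rose, and Piezo1, which fell. At an unadjusted p under 0.05 there were 2339 genes. DESeq2 called 14, among them both of these and Lyz2, and limma-voom called 2. With the library factor as a covariate, or with the length trend removed, edgeR called Lyz2 and neither of these. The count was 0 without piezo1ΔLysM replicate 1, where 2627 genes had an unadjusted p under 0.05. It was 1 without piezo1ΔLysM replicate 2, 4 or 5, or without piezo1fl/fl replicate 3 or 5.

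The title names Orai1, the pore of store-operated calcium entry, and Rac1, a small GTPase that drives actin at the engulfment cup. The values in both myeloid classes are RNA levels, and the activity of either protein was not measured. In monocytes/macrophages Orai1 was 38.0 ± 3.96 against 34.2 ± 1.67 CPM (log2 fold change 0.15, adjusted p = 0.344). Rac1 was 368 ± 5.96 against 356 ± 14.9 CPM (log2 fold change 0.05, adjusted p = 0.742). Mertk, a receptor for dying cells, was 21.8 ± 3.10 against 22.2 ± 3.06 CPM (log2 fold change -0.03, adjusted p = 0.918; 0.036 with the length trend removed). Orai1 had 0.042, Rac1 0.0026 and Mertk -0.18 with the library factor as a covariate, and with the length trend removed Orai1 had 0.056 and Rac1 0.10. Among 26 measured efferocytosis receptors and bridging molecules, 14 were higher and 12 lower in piezo1ΔLysM. The members with the smallest p were Trem2 (log2 fold change 0.29, adjusted p = 0.258) and C1qb (0.28, adjusted p = 0.287). Trem2 had 0.0063 and C1qb -0.018 with the library factor, and with the length trend removed C1qb had 0.12. No member passed in edgeR over all genes or adjusted over the list alone; 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The list had a camera adjusted p of 0.830.

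The genes that carry out engulfment through Rac and actin (38 measured) counted 22 lower and 16 higher. Rock2, a kinase of actomyosin contraction, was 81.6 ± 14.8 against 114 ± 12 CPM (log2 fold change -0.48, adjusted p = 0.248). Elmo1, which activates Rac with Dock proteins, had a log2 fold change of -0.26 (adjusted p = 0.248). The list had a camera adjusted p of 0.385; 9 members had an unadjusted p under 0.05, and 0 passed in edgeR over all genes or adjusted over the list alone, in DESeq2 or in limma-voom. Of 28 store-operated calcium genes, 19 were lower and 9 higher (camera adjusted p = 0.245). Itpr2, a calcium release channel of the endoplasmic reticulum, was 19.2 ± 2.36 against 24.1 ± 1.78 CPM (log2 fold change -0.33, adjusted p = 0.248), and Ppp3ca, a calcineurin subunit, had -0.31 (adjusted p = 0.248). In that list 5 members had an unadjusted p under 0.05, and edgeR over all genes or adjusted over the list alone, DESeq2 and limma-voom called 0. Of 27 mechanosensing genes, 18 were lower and 9 higher; Piezo1 was the 1 member called, over all genes and adjusted over the list alone. The integrin Itgb1 was 331 ± 48.1 against 419 ± 24.1 CPM (log2 fold change -0.34, adjusted p = 0.248). That list had a camera adjusted p of 0.487. Rock2 had -0.14, Elmo1 -0.066, Itpr2 -0.10, Ppp3ca -0.038 and Itgb1 -0.14 with the library factor as a covariate. With the length trend removed, Rock2 had -0.32, Elmo1 -0.17 and Itpr2 -0.095.

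Phagosome and lysosome genes (38 measured) counted 26 higher and 12 lower (camera adjusted p = 0.487). Rab5a, an early endosome GTPase, had a log2 fold change of -0.29 (adjusted p = 0.251), and Tfe3, a regulator of lysosome genes, -0.20 (adjusted p = 0.281). Of 36 inflammatory NF-κB genes, 15 were higher and 21 lower (camera adjusted p = 0.995). Nfkbia, the inhibitor of NF-κB, was 2312 ± 318 against 1774 ± 216 CPM (log2 fold change 0.38, adjusted p = 0.248), and the chemokine Ccl4 had 0.44 (adjusted p = 0.248). Of 30 repair genes, 13 were higher and 17 lower (camera adjusted p = 0.995); Sparc, a matrix protein, had 0.54 (adjusted p = 0.258). In these 3 lists 1, 6 and 3 members had an unadjusted p under 0.05. In edgeR over all genes or adjusted over the list alone, DESeq2 and limma-voom, 0 members of these lists passed. Rab5a had -0.019, Tfe3 0.0069, Nfkbia 0.24, Ccl4 0.076 and Sparc 0.055 with the library factor as a covariate. With the length trend removed, Tfe3 had -0.063 and Ccl4 0.26.

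Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were higher in piezo1ΔLysM monocytes/macrophages in 37 of 38 cases, with a mean log2 fold change of 0.17. Cox5a was 503 ± 121 against 388 ± 50.4 CPM (log2 fold change 0.38, adjusted p = 0.252) and Ndufb5 had 0.34 (adjusted p = 0.248). The list passed camera's preset test upward (adjusted p = 3.61e-05; adjusted p = 0.998 with an estimated correlation). Another 5 lists passed upward, and each had adjusted p = 0.998 with an estimated correlation. They were extracellular matrix and myofibroblast genes (25 of 32 higher, mean 0.30), fibroblast markers (9 of 10 higher, mean 0.39), cell cycle genes (22 of 28 higher, mean 0.16), interferon response genes (33 of 43 higher, mean 0.14) and immediate-early and heat shock genes (20 of 27 higher, mean 0.14). Their camera adjusted p-values were 0.000768, 0.00334, 0.00818, 0.0193 and 0.0254, and fry called 0 of the 28 lists, with 3 at an unadjusted p under 0.05. A monocyte/macrophage sub-cluster of 60 cells had Col1a1, Col3a1 and Sparc among its top genes and 6 fibroblast markers raised. It was not among the sub-clusters left out. Whether fibroblast RNA or cells in this class account for the matrix, fibroblast marker, Col1a1 and Sparc values was not tested.

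Named members of these lists stayed short of the threshold over all genes. Acta2, smooth muscle actin, was 16.6 ± 5.75 against 9.43 ± 2.69 CPM (log2 fold change 0.81, adjusted p = 0.248). Col1a1, a fibroblast collagen, was 26.2 ± 2.17 against 19.5 ± 3.11 CPM (log2 fold change 0.42, adjusted p = 0.248), and was the 1 fibroblast marker that passed adjusted over the list alone. Isg15, an interferon-induced ubiquitin-like protein, was 99.9 ± 24.6 against 47.6 ± 18.9 CPM (log2 fold change 1.07, adjusted p = 0.248), and Bst2, which tethers viruses, had 0.41 (adjusted p = 0.248). Tyms and H2afz of the cell cycle list had 0.45 and 0.28 (adjusted p = 0.256 and 0.254). Of the immediate-early list, Dusp1 had 0.42 and Fosl1 -0.42 (adjusted p = 0.248 each). Members at an unadjusted p under 0.05 numbered 8 for oxidative phosphorylation, 6 for matrix, 2 for fibroblast markers, 2 for cell cycle, 6 for interferon and 6 for immediate-early genes. With the library factor as a covariate, C1qb, Tfe3, Ndufb5, Cox5a and Tyms turned direction among the 28 genes named in monocytes/macrophages. Acta2 had 0.18 in that fit, H2afz 0.058, Dusp1 0.22 and Fosl1 -0.20, and with the length trend removed Bst2 had 0.24 and H2afz 0.14. Apart from Col1a1, 0 members of these 6 lists passed in edgeR over all genes or adjusted over the list alone, in DESeq2 or in limma-voom.

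The libraries also differed along transcript length in every class compared, and this moved with genotype. Across genes, which are not independent replicates, Spearman's correlation of the genotype log2 fold change with the longest transcript's length was -0.59 in monocytes/macrophages and -0.41 in neutrophils. Other measures of the libraries also differed in mean between genotypes, and 0 of 11 passed (smallest adjusted exact permutation p = 0.175, with 2 at an unadjusted p under 0.05). Malat1, a nuclear RNA, made up 0.802 ± 0.202% of UMIs in piezo1ΔLysM and 0.998 ± 0.0253% in piezo1fl/fl fibroblasts (exact p = 0.0238), and 1.11 ± 0.280% and 1.44 ± 0.105% in endothelial cells (exact p = 0.0397). Samples held 9.59e+07 ± 7.82e+06 against 8.06e+07 ± 1.42e+07 UMIs (exact p = 0.0714), and 6.65 ± 0.791% against 4.85 ± 1.90% of barcodes were over the mitochondrial limit (exact p = 0.0952). With the trend removed, the oxidative phosphorylation mean in monocytes/macrophages was 0.06 (camera adjusted p = 0.0945), and the interferon (0.11, adjusted p = 0.0522) and immediate-early calls (0.11, adjusted p = 0.0945) ended. With the library factor as a covariate the oxidative phosphorylation mean reversed to -0.13 (adjusted p = 1.22e-07). That factor moved with genotype, so such a fit cannot tell a library cause from a genotype effect shared by the classes. With that covariate the matrix (0.16, adjusted p = 0.0963), fibroblast marker (0.05, adjusted p = 0.742), cell cycle (0.06, adjusted p = 0.425) and immediate-early calls (0.09, adjusted p = 0.295) also ended.

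The interferon call in monocytes/macrophages ended without piezo1ΔLysM replicate 2 (adjusted p = 0.534) or 3 (0.0916), and without piezo1fl/fl replicate 2 (0.0695), 3 (0.0535), 4 (0.113) or 5 (0.121). The cell cycle call ended without piezo1ΔLysM replicate 1 (0.164) or piezo1fl/fl replicate 1 (0.18) or 2 (0.0695). The immediate-early call ended without piezo1ΔLysM replicate 2 (0.0927) or 3 (0.0517), or piezo1fl/fl replicate 2 (0.0695) or 5 (0.160). Single libraries also moved the means by more than 1.5 times. Without piezo1fl/fl replicate 4 the matrix mean was 0.14 and the fibroblast marker mean 0.24 (adjusted p = 0.0340 and 0.0335). The oxidative phosphorylation mean was 0.096 without piezo1ΔLysM replicate 4 and 0.11 without replicate 5. The cell cycle mean was 0.10 without piezo1ΔLysM replicate 1, and 0.074 and 0.29 without piezo1fl/fl replicates 1 and 5. The interferon mean was 0.071 without piezo1ΔLysM replicate 2 and 0.22 without piezo1fl/fl replicate 1. The number of called lists was 3 without piezo1fl/fl replicate 2. The other 22 lists had camera adjusted p-values of 0.245 or more.

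**Figure D2:**
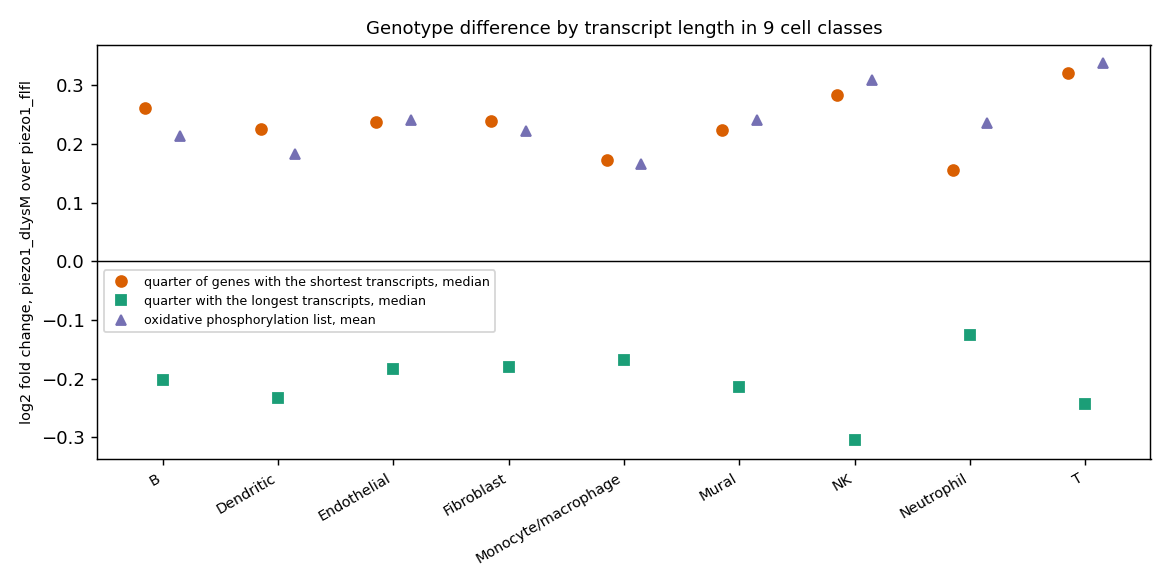
Log2 fold change, piezo1_dLysM (piezo1ΔLysM) over piezo1_flfl (piezo1fl/fl), on the y axis for 9 cell classes on the x axis: the median over the genes in the lowest quartile of transcript length (circles), that over the highest quartile (squares) and the mean of the oxidative phosphorylation list (triangles). Circles lie between 0.16 and 0.32 and squares between -0.30 and -0.13, and triangles lie above 0 in all 9 classes without length correction or covariate.

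In neutrophils the genotypes differed in the lysozyme genes. Lyz2 fell by 0.80 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0218), from 696 ± 121 to 399 ± 47.0 CPM, a level 42.6% lower with no overlap between groups. Lyz1 rose from 0.631 ± 0.475 to 4.78 ± 1.27 CPM (log2 fold change 3.0, SE 0.45, adjusted p = 0.00528); at 84 UMIs over all samples it lies below the 10 CPM of the naming rule, and was singled out after its values were seen. These were the 2 genes called among 8384, and 1290 had an unadjusted p under 0.05. DESeq2 called 42, among them Lyz2 but not Lyz1, and limma-voom called the same 2 genes. Without a count filter 108 were called, including both, and among them Isg15, Bst2, Ifit1, Birc5, Fpr2 and Orai2. Without piezo1fl/fl replicate 2 edgeR called 0, with 1306 genes at an unadjusted p under 0.05. In that fit Lyz1 had a log2 fold change of 2.80 (adjusted p = 0.0507) and Lyz2 -0.79 (0.0586). The Lyz2 call also ended without piezo1ΔLysM replicate 3 (-0.73, adjusted p = 0.126) or 5 (-0.80, 0.0512). The count was 1 without piezo1ΔLysM replicate 3, 4 without piezo1ΔLysM replicate 2, 6 without piezo1fl/fl replicate 3 and 5 without piezo1fl/fl replicate 5.

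Orai1 in neutrophils was 84.4 ± 19.4 against 65.8 ± 10.4 CPM (log2 fold change 0.37, adjusted p = 0.249) and Rac1 was 299 ± 32.5 against 298 ± 30.7 CPM (0.01, adjusted p = 0.986). With the library factor as a covariate Orai1 had 0.056 (adjusted p = 0.988) and Rac1 turned to -0.20 (adjusted p = 0.917). Mertk was near the floor, with 26 UMIs over all samples, and did not enter the test. Of 25 store-operated calcium genes, 14 were lower and 11 higher (camera adjusted p = 0.431). Stim1, the calcium sensor that opens Orai1, was 12.1 ± 2.58 against 17.9 ± 1.41 CPM (log2 fold change -0.54, adjusted p = 0.165), and Orai2 had -0.53 (adjusted p = 0.172). Of 36 engulfment and actin genes, 22 were lower and 14 higher (camera adjusted p = 0.211), with -0.33 for Abi1 (adjusted p = 0.230), a subunit of the WAVE actin regulator, and -0.31 for Elmo1 (adjusted p = 0.261). These lists had 4 and 3 members at an unadjusted p under 0.05, and 0 in filtered edgeR over all genes or adjusted over the list alone, in DESeq2 and in limma-voom. Without a count filter edgeR called Orai2 (-0.53, adjusted p = 0.0374). Orai2 had -0.14, Abi1 -0.17 and Elmo1 -0.080 with the library factor as a covariate.

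Granule genes of neutrophils were lower in piezo1ΔLysM in 19 of 20 cases, with a mean log2 fold change of -0.43. The list passed camera's preset test downward (adjusted p = 0.000409; adjusted p = 0.757 with an estimated correlation). Without piezo1fl/fl replicate 5 the mean was -0.24 (adjusted p = 0.0377). Lyz2 was called over all genes, and Lyz2 and Mmp25, a membrane metalloproteinase (log2 fold change -0.47, adjusted p = 0.173 over all genes), were called adjusted over the list alone. Mechanosensing genes were lower in 17 of 21 cases, with a mean of -0.14, and passed downward (adjusted p = 0.0115; adjusted p = 0.599 with an estimated correlation). Its integrins Itgb1 and Itgam had -0.36 and -0.39 (adjusted p = 0.186 and 0.199), and 0 members passed in filtered edgeR over all genes or adjusted over the list alone, in DESeq2 or in limma-voom, with 8 at an unadjusted p under 0.05. Without a count filter edgeR called 1 member, Edn1, named here after its values were seen. The mechanosensing call ended with the length trend removed (-0.11, adjusted p = 0.0544) and with the library factor as a covariate (-0.08, adjusted p = 0.0832; -0.21 for Itgb1 and -0.16 for Itgam).

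Another 4 lists passed upward in neutrophils, each with adjusted p = 0.757 with an estimated correlation. Oxidative phosphorylation genes were higher in 37 of 38 cases (mean 0.24, camera adjusted p = 1.29e-05), with Cox5a at 0.47 (adjusted p = 0.156). Immediate-early and heat shock genes were higher in 22 of 27 cases (mean 0.27, adjusted p = 0.00251), and Hspe1, Hsph1 and Ier2 passed adjusted over the list alone. Hspe1, a mitochondrial chaperonin, had 0.47 (adjusted p = 0.156 over all genes), and Ier2 0.45 (0.163). Interferon response genes were higher in 25 of 35 cases (mean 0.21, adjusted p = 0.0115), and Isg15, Bst2 and Ifit1 passed adjusted over the list alone. Isg15 was 176 ± 29.5 against 82.2 ± 32.4 CPM (log2 fold change 1.11, adjusted p = 0.156 over all genes) and Bst2 had 0.71 (0.120). Cell cycle genes were higher in 16 of 20 cases (mean 0.25, adjusted p = 0.0115), Tyms and Birc5 passed adjusted over the list alone, and Tubb5 and Stmn1 had 0.28 and 0.33 (adjusted p = 0.243 and 0.351 over all genes).

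Over all genes, with all 10 libraries and the count filter, 0 members of these 4 lists were called by edgeR or limma-voom. Without a count filter edgeR called Isg15 (1.12, adjusted p = 6.31e-09), Bst2 (0.72, adjusted p = 0.000767), Ifit1, Ifit3b and Birc5, and without piezo1fl/fl replicate 5 it called Isg15 (0.93, adjusted p = 0.0424). DESeq2 called 2 interferon genes, Isg15 and Bst2, and 0 of the other 3 lists, and 8, 13, 8 and 4 members had an unadjusted p under 0.05. With the library factor as a covariate the oxidative phosphorylation mean reversed to -0.04 (adjusted p = 0.371) and the immediate-early call ended (0.11, adjusted p = 0.101). In that fit Cox5a had 0.13, Hspe1 0.24, Ier2 0.19, Bst2 0.45 and Stmn1 0.053, and with the length trend removed Hspe1 had 0.30, Ier2 0.29 and Stmn1 0.17. The interferon call ended without piezo1ΔLysM replicate 4 (adjusted p = 0.0704) or piezo1fl/fl replicate 4 (0.0822) or 5 (0.147). The cell cycle call ended without piezo1ΔLysM replicate 1 (0.0976) or 3 (0.0862), or piezo1fl/fl replicate 4 (0.117). The interferon mean was 0.14 without piezo1ΔLysM replicate 4 and 0.32 without piezo1fl/fl replicate 1, and the cell cycle mean 0.13 without piezo1fl/fl replicate 4. Fry called 0 of the 26 lists, with 2 at an unadjusted p under 0.05.

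Neutrophil activation and ageing genes counted 13 higher and 17 lower of 30 (camera adjusted p = 0.394). The formyl peptide receptor Fpr2 had -0.57 (adjusted p = 0.184; -0.56 and 0.0164 without a count filter). Of 34 inflammatory NF-κB genes, 24 were lower and 10 higher (camera adjusted p = 0.378), with -0.42 for Nfkb1 (adjusted p = 0.209) and 0.34 for the cytokine Osm (0.271). Of 9 NADPH oxidase genes, 5 were higher and 4 lower (camera adjusted p = 0.666); Cyba had 0.34 and Cybb -0.39 (adjusted p = 0.272 each), and Cyba turned to -0.020 with the library factor as a covariate. In that fit Fpr2 had -0.19, Nfkb1 -0.16 and Cybb -0.18, and with the length trend removed Cyba had 0.16. The lists that did not pass had camera adjusted p-values of 0.0600 or more.

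Whether the genotype effect differed between monocytes/macrophages and neutrophils was tested on the per-sample difference of both classes. The Piezo1 log2 fold change was lower in monocytes/macrophages than in neutrophils by a difference of -0.30 (limma adjusted p = 0.705). The Lyz1 difference was 1.48 (adjusted p = 0.495), those of Lyz2, Orai1 and Rac1 were 0.13, -0.20 and 0.05 (adjusted p = 0.873, 0.768 and 0.934), and Mertk entered no test in neutrophils. Limma called 0 of 8253 genes, with 612 at an unadjusted p under 0.05, and no other tool was run on this difference. The effects in both classes are thus not shown to differ.

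In the other 7 classes edgeR called 3 genes. In B cells Klf2, a transcription factor of lymphocyte quiescence, rose from 304 ± 76.0 to 577 ± 161 CPM (log2 fold change 0.93, adjusted p = 0.0441). Sdhaf1, an assembly factor of respiratory complex II, rose there from 112 ± 30.8 to 209 ± 27.2 CPM (log2 fold change 0.87, adjusted p = 0.0441). In fibroblasts Lyz1 rose from 0.0385 ± 0.0413 to 0.903 ± 0.378 CPM (log2 fold change 4.25, adjusted p = 0.0303), on 158 UMIs in all; it lies below 10 CPM and was named because it is 1 of few calls. Dendritic, endothelial, mural, NK and T cells had 0 calls in edgeR, with 1621, 1935, 1323, 314 and 737 genes at an unadjusted p under 0.05. DESeq2 called 29, 166, 3, 0 and 11 in these, 4 in B cells and 2 in fibroblasts.

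These calls depended on which libraries were included. The total of 3 became 86 without piezo1ΔLysM replicate 1, 42 without piezo1ΔLysM replicate 2 and 282 without piezo1fl/fl replicate 5; it was 0 without piezo1ΔLysM replicate 5 or piezo1fl/fl replicate 1 or 2, and 1 without piezo1ΔLysM replicate 3 or piezo1fl/fl replicate 3 or 4. With 1 library left out, Klf2 kept its call without piezo1ΔLysM replicate 1 or 2 or piezo1fl/fl replicate 5, and had adjusted p = 0.0907 to 0.197 without each other library. Sdhaf1 kept its call without piezo1ΔLysM replicate 2 or 4 or piezo1fl/fl replicate 3 or 5, and had adjusted p = 0.0608 to 0.182 without each other library. Fibroblast Lyz1 kept its call without piezo1ΔLysM replicate 2 or 3, and had adjusted p = 0.0698 to 0.199 without each other library. The log2 fold changes in these fits kept their direction. They were 0.78 to 1.08 for Klf2, 0.79 to 1.05 for Sdhaf1 and 3.94 to 4.81 for fibroblast Lyz1. With the length trend removed, B cells and fibroblasts had 0 calls, with 555 and 1833 genes at an unadjusted p under 0.05. In that fit Klf2 had 0.75 and Sdhaf1 0.78 (adjusted p = 0.0546 each), and fibroblast Lyz1 had 4.06 (0.0544). Fibroblast Lyz1 also lost its call with the replicate number as a block (4.21, adjusted p = 0.246).

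Cell composition was compared as the share of each class among the kept cells of a sample. Monocytes/macrophages made up 35.8 ± 1.85% of piezo1ΔLysM and 35.0 ± 5.70% of piezo1fl/fl cells (two-sided exact permutation p = 0.786). Neutrophils made up 22.5 ± 2.32% and 24.4 ± 5.45% (exact p = 0.603). Fibroblasts made up 11.4 ± 1.6% and 10 ± 1.2% (exact p = 0.151), endothelial cells 4.92 ± 2.10% and 4.37 ± 0.832% (exact p = 0.794), and B cells 3.47 ± 0.679% and 4.06 ± 1.29% (exact p = 0.397). Over the 13 named classes the smallest adjusted p was 0.735, and 0 had an unadjusted p under 0.05. Neutrophils among both myeloid classes together were 38.5 ± 2.19% and 41.0 ± 7.60% (exact p = 0.714), with a difference of -2.48 points that turned to 0.841 without piezo1fl/fl replicate 2. Unnamed cells were 13.5 ± 2.02% and 12.3 ± 1.83% (exact p = 0.317). The labels state no sort, so shares are those of the cells loaded.

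**Figure D3:**
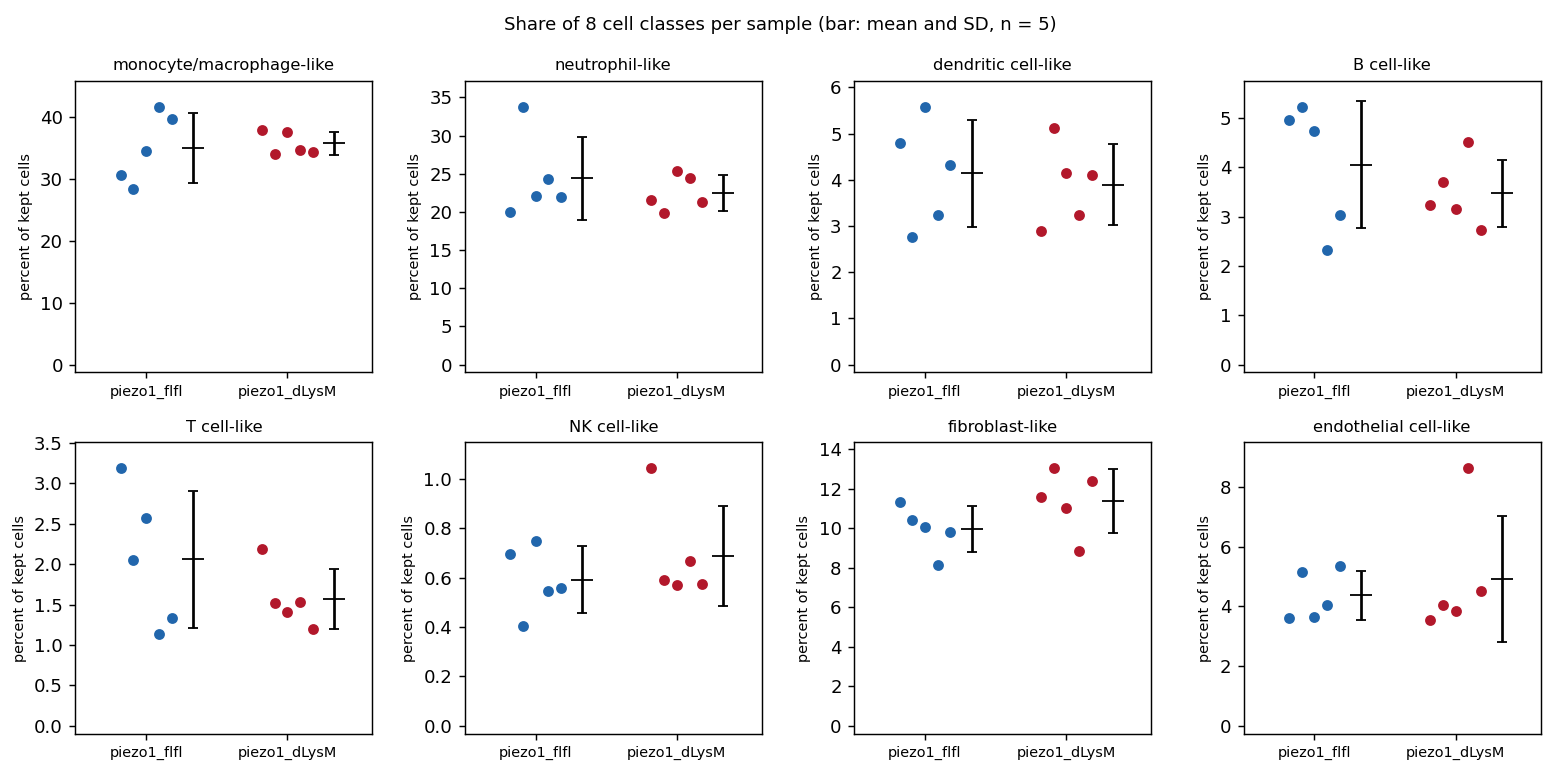
Percent of kept cells (y axis) in 8 cell classes for each sample, by genotype (x axis; piezo1_flfl is piezo1fl/fl and piezo1_dLysM is piezo1ΔLysM). Points are samples and bars give mean and SD, n = 5; the genotypes overlap in all 8 classes shown, and piezo1fl/fl replicate 2 is the highest neutrophil sample at 33.8%.

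Within monocytes/macrophages, sub-clusters resembled macrophages high in Trem2, Spp1 and Gpnmb (5902 cells, plus 1203 and 1910 cycling cells), MHC class II-high macrophages (5085), Ly6c2-high monocytes (2719), interferon-responsive cells (2557) and resident macrophages (626). Piezo1 was lower in piezo1ΔLysM in all 9 sub-clusters tested, with log2 fold changes from -0.35 to -1.03. It passed in 8 of the 9 when adjusted over the 11 myeloid sub-clusters with enough Piezo1 counts. The largest difference was in the resident-like cells, at 21.4 ± 10.1 against 45.6 ± 9.95 CPM (log2 fold change -1.03, edgeR adjusted p = 0.000550 over sub-clusters). These were the fewest cells of the 9, and Piezo1 was not called there over all genes (edgeR adjusted p = 0.344). Whether the change differed between sub-clusters was not tested. The sub-cluster marked by Saa3 and Arg1 had the smallest (-0.35, adjusted p = 0.123, edgeR). Lyz1 was higher in all 9 and passed in 8, and Lyz2 was lower in 9 of 9 and passed in 9 when adjusted over sub-clusters. Over all genes edgeR called Piezo1 in 3 of the 9, Lyz1 in 5 and Lyz2 in 1. Of the 2 neutrophil sub-clusters with enough Piezo1 counts, SiglecF-high-like cells had -0.61 (edgeR adjusted p = 0.0209 over sub-clusters), and cells marked by Retnlg and S100a8 had 0.06 (edgeR adjusted p = 0.80); neither was called over all genes.

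Shares of sub-clusters were compared only where their defining genes did not themselves differ between genotypes. The Trem2, Spp1 and Gpnmb-high-like cells that were not cycling made up 26.3 ± 5.72% of monocytes/macrophages in piezo1ΔLysM and 19.0 ± 6.05% in piezo1fl/fl (exact p = 0.0873). The cycling sub-clusters of that name made up 4.96 ± 0.930% and 4.37 ± 1.63% (exact p = 0.468), and 7.97 ± 2.67% and 6.76 ± 2.85% (exact p = 0.484). Resident-like macrophages made up 1.98 ± 0.734% and 3.11 ± 0.934% (exact p = 0.103), and Ly6c2-high monocyte-like cells 9.82 ± 3.20% and 11.9 ± 3.08% (exact p = 0.317). Of the 8 monocyte/macrophage sub-clusters compared 0 passed: the smallest adjusted p was 0.339, and 0 had an unadjusted p under 0.05. The neutrophil sub-cluster marked by Retnlg and S100a8 was 35.5 ± 6.82% and 36.3 ± 11.9% of neutrophils (exact p = 0.913). Interferon-responsive-like cells of both classes were not compared, because Isg15, which defines them, differed within them.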

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

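The tests of the length trend, of the LysM-Cre explanation, of shared lysozyme reads, of Isg15 against length and sub-clusters and of Piezo1 across classes were chosen after the results were seen; the chromosome 10 test and the Isg15 test against free RNA were not.

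Short transcripts were higher and long transcripts lower in piezo1ΔLysM, and oxidative phosphorylation genes were higher with them. A change made in LysM-Cre myeloid cells would be larger there than elsewhere, but the median over the 7 other classes of the oxidative phosphorylation mean was 0.24 on the log2 scale, above the 0.17 of monocytes/macrophages. With each sample's trend on transcript length removed, the monocyte/macrophage mean dropped to 0.0592 and its list call ended. Removing the trend lowers any list that follows it, whatever made the trend. The drop therefore cannot tell a library cause from a biological one. The trend's own origin stays open: the labels give no library date or batch, all 3 of the highest library factors (0.40, 1.11 and 2.06) belong to piezo1ΔLysM replicates 3, 5 and 4, and other library measures, such as UMIs per sample and the Malat1 share, differed in mean with genotype (smallest of 11 adjusted exact p-values 0.175). A difference of genotype acting on every cell type was not tested apart from it.

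Lyz1 was higher and Lyz2 lower in piezo1ΔLysM, which could come from Lyz2 reads assigned to its near-identical neighbour. That would give both myeloid classes a like ratio of Lyz1 to Lyz2. The ratio in monocytes/macrophages was on average 1.74 times that in neutrophils, in the same direction in all 5 piezo1ΔLysM samples. However, the neutrophil ratio rests on 13 to 17 Lyz1 UMIs per sample. Pooled over these samples, the ratio was 2.01% in monocytes/macrophages and 1.16% in neutrophils. It was 2.17% in dendritic cells, 2.17% in endothelial cells and 1.79% in fibroblasts, also on few Lyz1 UMIs. A share of Lyz2 reads that is the same in both genotypes would make Lyz1 follow Lyz2. In monocytes/macrophages Lyz1 was 110 ± 13.8 CPM in piezo1ΔLysM and 9.91 ± 6.84 CPM in piezo1fl/fl. Lyz2 was 5454 ± 1023 and 8625 ± 1222 CPM. These values argue against such a fixed share in that class. A share of reads that differs with the allele stays open. A chromosome 10 segment carried along with the Cre allele cannot be told apart from the allele, which it would follow in every sample: 18.2% of 44 genes within 5 Mb had an unadjusted p under 0.05, against a median of 18.2% (SD 5.87) over windows elsewhere. The Cre insertion in Lyz2 is a biological explanation that the design names, and it stays untested, as the files hold no reads.

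Isg15 was higher in piezo1ΔLysM in 7 classes where it was measured well enough, by 1.07 to 1.88 on the log2 scale; edgeR as set for the comparisons called it over all genes in none of these, while DESeq2 called it in neutrophils (1.09, adjusted p = 0.00229) and mural cells. EdgeR also called it without a count filter in neutrophils, mural and T cells, with the replicate block in dendritic and T cells, without piezo1fl/fl replicate 5 in neutrophils (0.93, adjusted p = 0.0424) and mural cells, without piezo1fl/fl replicate 4 in mural cells and without piezo1ΔLysM replicate 2 in T cells. Against the length trend as the whole cause, the monocyte/macrophage value was 0.88 with the trend removed and 1.07 before, and against more interferon-responsive cells the median change over monocyte/macrophage sub-clusters was 0.91. Free neutrophil RNA would carry S100a8 along, but the Isg15 difference in fibroblasts was 37.3% of that in neutrophils while their S100a8 was 0.0967% of the neutrophil level, a ratio of 385 (463 in endothelial cells). A response to interferon that differs with genotype may be a hypothesis, and an unlabelled difference between the animals or libraries stays open and untested.

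In 11 of 156 groups of 5 samples, 1 sample stood apart by its gap over the whole range, where chance gives about 1 in 20. The gap in monocytes/macrophages was 0.779 for Col1a1 (piezo1fl/fl replicate 4 lowest, 14.1 CPM), 0.788 for Sparc (the same sample lowest, 12.3 CPM) and 0.836 for Lyz1 (the same sample highest, 22.0 CPM). In neutrophils it was 0.840 for Ier2, again with piezo1fl/fl replicate 4 highest (287 CPM). Among shares it was 0.777 for cardiomyocytes in piezo1ΔLysM replicate 3 (0.0259%, lowest) and 0.740 in piezo1fl/fl replicate 1 (0.684%, highest). It was 0.810 for endothelial cells in piezo1ΔLysM replicate 4 (8.62%, highest), 0.793 for NK cells in piezo1ΔLysM replicate 1 (1.04%, highest) and 0.724 for Schwann cells in piezo1fl/fl replicate 3 (0.212%, highest). It was 0.794 for neutrophils among both myeloid classes in piezo1fl/fl replicate 2 (54.3%, highest). It was 0.939 for resident-like macrophages in piezo1fl/fl replicate 5 (1.44%, lowest).

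The Piezo1 change differed between cell classes in 3 of 6 exact permutation tests against monocytes/macrophages. The difference of log2 changes was -0.59 from endothelial cells and -0.42 from fibroblasts (adjusted exact p = 0.0238 each, unadjusted 0.00794, the smallest possible), and -0.50 from dendritic cells (adjusted exact p = 0.0476). From mural cells, neutrophils and B cells it was -0.51, -0.30 and -0.35 (adjusted exact p = 0.0595, 0.133 and 0.183). These classes had 187, 567 and 138 Piezo1 UMIs over all samples, against 14298 in monocytes/macrophages.

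In cells that met no marker list, which entered no comparison, Lyz1 was 28.1 ± 8.47 CPM in piezo1ΔLysM and 3.02 ± 2.39 CPM in piezo1fl/fl (n = 5 each). The value was listed because the groups did not overlap. That alone gives the smallest possible exact permutation p (0.00794), so this p adds no support. An unnamed cluster of 1872 cells had C1qa, C1qb and Apoe among its top genes. The value is therefore not shown to be independent of monocytes/macrophages.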

How the results depend on the processing

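The covariate fits, the length correction, the sub-clusters left out and the 4 libraries left out were alternatives chosen after seeing the data; the others were fixed before. The library factor moved with genotype, so calls lost or directions turned in the covariate fits do not by themselves show a library cause.

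For 90 named values, 1001 alternatives were run: 888 kept direction and side of the threshold, 63 lost a call, 14 gained one and 36 turned direction, the last in 17 values. A value that was never called, such as Orai1 or a class share, counts as kept while it stays uncalled in the same direction. The 888 therefore do not measure how well calls held. Of the fits with 1 library left out, this tally holds only those with the lowest and highest value, so it undercounts lost calls. Over all 10 such fits, calls ended in 6 for monocyte/macrophage Lyz1, 6 for Sdhaf1 and 7 for Klf2. For neutrophil Lyz1 the call ended in 1 of the 10. The count of genes differing between both myeloid classes stayed at 0 in limma under every alternative run, with 425 to 819 genes at an unadjusted p under 0.05, as did the counts of class and sub-cluster shares. Where the cause is not named, it was not tested.

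In monocytes/macrophages the count of 2 genes became 14 with DESeq2 and 0 with the replicate block (2257 genes at an unadjusted p under 0.05). It was 1 without a filter, with the library factor, with the length correction or without cycling sub-clusters, and 0 to 2 with 1 library left out. The 6 lists became 0 with an estimated correlation or fry, and 3 to 7 with 1 library left out. In neutrophils the 2 genes became 42 with DESeq2, 108 without a filter and 5 with the replicate block. They became 1 with stricter cells, equal cells or the most varying sub-cluster left out, and 0 without 4 libraries (618 genes at an unadjusted p under 0.05). They were 0 to 6 with 1 library left out. The 6 lists became 10 with 1 or 2 library factors and 0 with an estimated correlation or fry. In other classes the 3 genes became 215 with DESeq2, 233 without a filter and 11 with the replicate block, and were 0 to 282 with 1 library left out.

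The log2 fold change of Piezo1 in monocytes/macrophages (-0.67) lost its call with the replicate block (-0.67, edgeR adjusted p = 0.135), 1 or 2 library factors (-0.67 and -0.66, adjusted p = 0.0552 and 0.0599), the length correction (-0.49, adjusted p = 0.331) and without 4 libraries (-0.69, adjusted p = 0.165, with fewer samples). It was -0.71 to -0.64 with 1 library left out.

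Oxidative phosphorylation means turned to -0.13 and -0.14 with 1 and 2 library factors and -0.085 without 4 libraries in monocytes/macrophages, and to -0.044, -0.062 and -0.062 in neutrophils. Fibroblast markers in monocytes/macrophages turned to -0.063 without 4 libraries. Rac1 in neutrophils (0.01) turned to -0.0044 with DESeq2, -0.0045 with RLE factors, -0.014 with stricter cells, -0.024 with equal cells and -0.012 without the most varying sub-cluster. It turned furthest, to -0.20 and -0.19, with 1 and 2 library factors, and to -0.11 without 4 libraries. Cyba in neutrophils turned to -0.020 and -0.033 with 1 and 2 library factors. In monocytes/macrophages these turned C1qb to -0.018 and -0.024, Tfe3 to 0.0069 and 0.0099, Ndufb5 to -0.0018 and -0.0014 and Cox5a to -0.087 and -0.092. Tyms turned to -0.00067 with 1 library factor, and Mertk to 0.036 with the length correction. With 1 library left out Rac1 in neutrophils was -0.031 to 0.068, and Mertk in monocytes/macrophages was -0.098 to 0.048.

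With 1 library left out, the genotype difference in points of share was -3.84 to 0.841 for neutrophils among both myeloid classes, -0.587 to 0.119 for dendritic and -0.377 to 0.893 for endothelial cells. It was -0.900 to 2.43 for monocytes/macrophages, -0.191 to 0.156 for mural cells, -3.04 to 0.414 for neutrophils and -4.48 to 2.55 for the neutrophil sub-cluster marked by Retnlg and S100a8. Mural cells turned to -0.0203 with stricter cells.

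Depth limits Lyz1 in neutrophils (84 UMIs) and in fibroblasts (158 UMIs). It also limits Piezo1 in B cells (138 UMIs) and mural cells (187 UMIs).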

Other observations

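The tests on Piezo1 across classes and on fibroblast Lyz1 were chosen after the results were seen, and the counts over other splits of the samples were not.

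Outside the 2 myeloid classes gene lists passed camera's preset test, but 0 passed in any of these 7 classes with an estimated correlation (1 list in B cells and 1 in NK cells had an unadjusted p under 0.05), so they are not shown to differ apart from correlation among their genes. Upward passed 7 lists in B, 6 in T, 4 in dendritic, 2 in fibroblasts, 2 in mural, 1 in endothelial and 1 in NK cells, and downward 1 each in fibroblasts, mural and NK cells. Fry called 1 list, mechanosensing genes in NK cells (adjusted p = 0.0411). In dendritic cells interferon response genes were higher in 39 of 41 cases (mean log2 fold change 0.56, camera adjusted p = 1.84e-08; adjusted p = 0.737 with an estimated correlation), and Ifi213, Zbp1, Isg15, Bst2, Ifi47 and Rtp4 passed adjusted over the list alone. In T cells they were higher in 18 of 20 cases (mean 0.43, adjusted p = 0.00466; adjusted p = 0.411 with an estimated correlation), with Zbp1, Isg15, Bst2 and Ifi47 called adjusted over the list alone. In mural cells cell cycle genes were higher in 27 of 28 cases (mean 0.85, adjusted p = 1.31e-08; adjusted p = 0.764 with an estimated correlation). In B cells inflammatory NF-κB genes were higher in 15 of 20 cases (mean 0.30, adjusted p = 0.00196; adjusted p = 0.358 with an estimated correlation), and Icam1, Tnfaip3, Ccl2, Ccl7 and Nfkbia passed adjusted over the list alone. Oxidative phosphorylation genes passed camera's preset test upward in all 7 of these classes, with means from 0.18 to 0.34 and adjusted p = 0.411 to 0.978 with an estimated correlation. The lists that passed downward were mechanosensing genes in fibroblasts (26 of 29 lower, mean -0.14, adjusted p = 0.0340; 0.922 with an estimated correlation) and NK cells (8 of 10 lower, mean -0.35, adjusted p = 0.0275; 0.352), and immediate-early genes in mural cells (22 of 27 lower, mean -0.25, adjusted p = 0.00366; 0.764). Other splits of the samples were not fitted for lists in these classes.

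Lyz2 in dendritic cells, a class related to monocytes, was 480 ± 102.7 against 811 ± 146 CPM (log2 fold change -0.76, edgeR adjusted p = 0.0908). DESeq2 called it, as did edgeR without a count filter and with the length trend removed, the last chosen after seeing the data. In endothelial cells Orai1 was 111 ± 17.7 against 83.9 ± 12.4 CPM (log2 fold change 0.40, adjusted p = 0.171). Orai1 was higher in piezo1ΔLysM in all 9 monocyte/macrophage and all 4 neutrophil sub-clusters tested; adjusted over these 13, it passed in Ly6c2-high monocyte-like cells (log2 fold change 0.39) and in 2 neutrophil sub-clusters (0.49 and 0.47), each at adjusted p = 0.0466. Over all genes edgeR, the 1 tool run there, called it in 0 of the 13, with 4 at an unadjusted p under 0.05. With the library factor as a covariate, a fit chosen after seeing the data, the Orai1 log2 fold change dropped to 0.056 in neutrophils (adjusted p = 0.988) and 0.042 in monocytes/macrophages.

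A hypothesis is that the Piezo1 difference was made by LysM-Cre in myeloid cells. It needs a larger change there than in classes without LysM-Cre, and the endothelial contrast, which prompted it, cannot test it. The log2 change in monocytes/macrophages minus that in fibroblasts was -0.42 (adjusted exact permutation p = 0.0238), with 8444 Piezo1 UMIs in fibroblasts over all samples. From mural cells it was -0.51 (adjusted exact p = 0.0595) and from B cells -0.35 (adjusted exact p = 0.183). These classes had 187 and 138 Piezo1 UMIs. Depth thus limits both contrasts, which do not count against the hypothesis, and it stays open. That Piezo1 lay between 30.3 and 34.4 CPM and not near 0 is open between incomplete deletion and transcripts counted from a part that is not deleted.

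A second hypothesis is that fibroblast Lyz1 was free RNA of monocytes/macrophages. Pooled over the piezo1ΔLysM samples, the ratio of Lyz1 to Lyz2 in fibroblasts was 0.890 times that in monocytes/macrophages, near the ratio that a shared source would give. Reads shared between both genes would also give a like ratio, so the test cannot tell these apart. Free RNA would carry the Lyz2 change too. Lyz2 had a log2 fold change of -0.26 in fibroblasts (edgeR adjusted p = 0.715) and -0.66 in monocytes/macrophages (0.248). The hypothesis stays open.

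Other splits of the samples into 5 and 5 were fitted in the same way, 100 of the 126 with the real one among them. For the genes called in monocytes/macrophages, 4 splits gave at least the real 2 and the highest other gave 8. In neutrophils 4 splits gave at least the real 2 and the highest other gave 6. Few splits thus reached the real counts in these classes, but some regroupings gave more calls, so chance is not excluded there. For the other classes chance was not excluded either: 12 splits gave at least the real 3, and the highest other gave 617. That split exchanged piezo1ΔLysM replicate 1 with piezo1fl/fl replicate 5 and kept all other samples with their genotype. The real comparison gave 86 calls without the first of these libraries and 282 without the second. Whether a structure of the samples other than genotype made the 617 calls was not tested. Chance was also not excluded for gene lists. In monocytes/macrophages 65 splits lay at or above the real 6 (highest other 17), and in neutrophils 39 did (real 6, highest other 11). For the class difference the real count was 0, which all 100 splits reach by construction (highest other 4), so this count says nothing about chance.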
